A study of Homo sapiens with 6 samples.

How the data were processed

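RNA was extracted from xenograft tumours of PC-3 cells carrying a control hairpin (shGFP) or a hairpin against versican (shVCAN). It was sequenced as paired reads, per the labels' protocols. The labels number 3 xenografts in each of 2 groups, and each is called a tumour here. Trim Galore, STAR, DESeq2 and the build hg38 are named in the submitters' processing notes, without versions, roles or order. The authors deposited whole-number read counts per gene with versioned Ensembl identifiers, and these counts are not normalised. The counting program, its annotation release, its strand setting and any step that removes mouse reads are not given in the sources used here. If mouse reads were not removed, those that align to human genes would be counted as human. The growth protocol mentions a further experimental group, which was not analysed here.

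The table had 67071 rows. The 45 rows for second copies of pseudoautosomal genes held 0 counts and were left out, which left 67026 genes. A symbol table named 60370 identifiers and GENCODE 29 named another 289, while 6367 had no symbol and held at most 0.166% of the counts of a library. Coordinates, exonic length and GC content came from GENCODE 29 on GRCh38, the assembly also called hg38. Libraries held 11253058 to 13327617 counts. At that depth VCAN had between 39 and 133 counts per tumour, so its level carries more counting error than that of the abundant genes. Counts come from amplified libraries, and counting error alone does not cover the variation of amplification.

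Pairs of libraries were compared over genes with at least 50 summed counts. The chi-square per gene was 3.45 to 6.61 within groups and 48.9 to 83.5 between groups, more than counting error alone gives. This does not show whether libraries of a group came from separate tumours, and each was counted as 1 replicate as the labels number them. The common biological coefficient of variation was 6.63%, and the first principal component held 56.2% of the variance.

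Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (16254 genes kept) and group as the only term. A gene is called, or said to rise or fall, at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values use TMM library sizes, and log2 CPM a prior count of 2. VCAN and the share of counts in mitochondrial messenger RNAs were also tested by an exact two-sided permutation test.

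Before the data were examined, 37 gene lists were fixed, with VCAN in none. They cover partners of versican and hyaluronan, chondroitin sulfate synthesis, collagens and matrix glycoproteins, integrins and focal adhesion, matrix proteases, mesenchymal and epithelial genes, mitosis, DNA replication, hypoxia, glycolysis, interferon, inflammation, the unfolded protein response, cholesterol synthesis, WNT, TGF-beta and EGFR targets, p53 and apoptosis, the androgen receptor axis, neuroendocrine markers, the methyladenosine machinery, angiogenic factors and ribosomal proteins. Quality lists hold mitochondrial transcripts, nuclear noncoding RNAs, replication-dependent histones and dissociation stress genes. Cell type lists hold macrophages, neutrophils, endothelial cells, fibroblasts and pericytes, skeletal muscle, adipocytes, keratinocytes, erythroid cells and platelets, and lymphocytes. Older symbols were matched through GENCODE 29 and RefSeq synonyms, and 2 listed mouse symbols had no match. The RefSeq synonyms were added after a first run. They brought CEMIP2 (listed as TMEM2) into the list of versican and hyaluronan partners, and no call changed. Lists with at least 5 tested members (34) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The p-values were adjusted over the lists, and list members were also adjusted over the list alone.

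The rule for named genes was set before the data were examined. It takes VCAN, then among called genes with a proper symbol, a mean of at least 5 CPM in the higher group and groups that do not overlap the 10 largest rises and 10 largest falls, then up to 4 called members of each list with the smallest p (2 members for a list called by camera with no called gene). Some of the 147 genes this names are not reported here. Of the 147, 79 share no exonic base with another annotated gene, and in RN7SL1 and ITGB3 at least 50% of the exonic bases are shared.

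The alternatives were DESeq2 size factors, upper quartile factors, library size only, no filter, a filter of 1 CPM in 3 samples, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, each tumour left out in turn, an absolute log2 fold change of at least 1, and an adjusted p under 0.01. After seeing the data 3 were added. The first was an offset for each tumour's trend with exonic length and GC content (fitted on genes of at least 4 CPM outside all lists). The others were the same offset with the block, and scaling without mitochondrial genes. Length here is that of all annotated exons of a gene together, which can exceed the length of its messenger RNA. Length and GC content were known for 98.5% of the tested genes.

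The fit was tested on simulated data made from the means, dispersions and library sizes of the shVCAN against shGFP comparison (15906 genes in the simulated fit). It recovered 28.6% of genes changed 1.25-fold, 65.3% at 1.5-fold, 90% at 2-fold and 93.9% at 4-fold, and 7.69% of its calls were genes simulated without change. Camera called the 1 shifted list and 0 of 33 others. The simulated genes varied independently and the lists were random, so this does not test the preset correlation. The simulated fit called 156 genes, so its recovery need not hold for the data, where 40.3% of tested genes were called. A simulated length trend gave a Spearman correlation of −0.659 with length, and the offset brought it to −0.0181 while a list shifted by 0.32 had a median of 0.332. Tables were joined with pandas 2.3.3 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.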

Results

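The series measured gene expression in xenograft tumours grown under the skin of immunodeficient mice from PC-3, an established human prostate cancer cell line that lacks the androgen receptor response of many prostate tumours. The cells carried a lentiviral short hairpin RNA against GFP (shGFP, the knockdown control) or against VCAN (shVCAN), the gene for versican, a large chondroitin sulfate proteoglycan of the extracellular matrix. Each group had 3 numbered xenografts, called tumours here. Their libraries held 12936539, 11253058 and 11633764 counts in shGFP and 12959840, 13327617 and 13134546 counts in shVCAN. The comparison asks which transcripts differ between tumours with and without the knockdown of versican. Values are normalised read counts (CPM, scaled by TMM library sizes), given as mean ± SD with n = 3 per group, and log2 fold changes are shVCAN over shGFP with their standard error (SE).

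VCAN (ENSG00000038427.16, chromosome 5, 83471465 to 83582303, GRCh38) was lower in each shVCAN tumour than in every shGFP tumour. The shGFP tumours 1, 2 and 3 had 133, 104 and 121 VCAN counts, and the shVCAN tumours 1, 2 and 3 had 69, 39 and 44. The level was 10.6 ± 0.809 CPM in shGFP and 3.66 ± 1.19 CPM in shVCAN. That is a log2 fold change of −1.54 (SE 0.207, edgeR quasi-likelihood adjusted p = 4.59e-07). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 tumours allows. VCAN reads remained in all 3 knockdown tumours. Some VCAN reads of either group may be mouse reads, since it is not known whether mouse reads were removed. The fall in the PC-3 cells alone was therefore not measured.

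The expression difference between the groups reached far beyond VCAN. The matrix protein periostin (POSTN) rose from 12.2 ± 0.622 to 75.0 ± 6.51 CPM, and the granin SCG2, a secretory granule protein, rose from 6.72 ± 1.21 to 32.9 ± 0.716 CPM. Podocalyxin (PODXL), a sialomucin of the cell surface, fell from 1249 ± 50.2 to 157.4 ± 13.2 CPM, and the airway mucin MUC5B fell from 153 ± 22.5 to 15.8 ± 3.55 CPM. POSTN lies on chromosome 13 (37562583 to 37598844) and PODXL on chromosome 7 (131500262 to 131558217). The 13 messenger RNAs encoded in the mitochondrial genome fell from 14.9% ± 1.43 of all counts to 6.82% ± 0.701. Of 16254 genes tested, 3120 were higher and 3425 lower in shVCAN at an adjusted p under 0.05, and 450 and 435 of these differed at least 2-fold. The 2 groups did not overlap in 7910 genes (48.7%), where chance gives 10%. When libraries were scaled by their size alone, 5228 genes were higher and 1890 lower, so the share of calls that were higher was 73.5% in place of 47.7%. This scaling raised the median log2 fold change of the tested genes to 0.168.

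Among genes of at least 5 CPM in the higher group, the 10 largest rises were in ATCAY, RN7SL3, RAB39B, POSTN, NNAT, VAT1L, SEMA5A, CCDC198, SCG2 and CACNG4. ATCAY, a gene for a brain protein called caytaxin, had the largest fitted rise of these, from 0.42 ± 0.29 to 5.17 ± 1.13 CPM. The semaphorin SEMA5A rose from 2.09 ± 1.28 to 11.5 ± 0.998 CPM, and CACNG4, a calcium channel subunit, from 4.00 ± 1.13 to 18.3 ± 0.574 CPM. RN7SL3, an RNA of the signal recognition particle, had a log2 fold change of 2.94 (SE 0.126). That value is uncertain because near-identical copies can share the reads of RN7SL3. The 10 largest falls were in ADGRF5, SSTR5-AS1, BPIFA1, MUC5B, PODXL, SPARCL1, C5AR2, ARHGAP30, THBD and CDH5. The adhesion receptor ADGRF5 fell from 20.8 ± 5.4 to 1.13 ± 0.129 CPM. Thrombomodulin (THBD), an anticoagulant receptor, fell from 49.4 ± 5.52 to 7.31 ± 0.632 CPM, and the matrix protein SPARCL1 from 25.1 ± 3.98 to 3.16 ± 0.661 CPM. SSTR5-AS1 is an antisense transcript, and its value is uncertain because the strand setting of the counting is not given in the sources used here.

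Of 45 tested collagens and matrix glycoproteins, 29 fell, 7 rose and 9 were not called (30 and 7 adjusted over the list alone), with a median log2 fold change of −0.38. Camera placed the list lower than other genes (adjusted p = 2e-05, and adjusted p = 0.194 with an estimated correlation). The list of fibroblast and pericyte markers, which shares 6 tested genes with the matrix list, had a median of −0.60 (camera adjusted p = 0.00735, and adjusted p = 0.194 with an estimated correlation). After an offset for exonic length and GC content the median of the matrix list was −0.24. The fibrillar collagen chain COL1A2 fell from 72.1 ± 10.4 to 13.9 ± 2.78 CPM, COL3A1 from 80.2 ± 7.87 to 29.7 ± 4.48 CPM and COL6A1 from 3118 ± 127 to 1753 ± 175 CPM. Other collagen VI chains rose, COL6A2 from 1417 ± 32.2 to 1764 ± 149 CPM and COL6A3 from 231.1 ± 7.65 to 270.1 ± 16.1 CPM. Thrombospondin 2 (THBS2) rose from 30.02 ± 3.36 to 77.7 ± 4.49 CPM. Of 24 tested partners of versican and hyaluronan, 6 rose, 9 fell and 9 were not called (6 and 9 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.201). Tenascin C (TNC) fell from 369.6 ± 15.2 to 219.3 ± 9.93 CPM, the versican-cleaving protease ADAMTS9 from 61.4 ± 3.18 to 28.4 ± 1.38 CPM, and the hyaluronan synthase HAS3 and the hyaluronan-degrading CEMIP had log2 fold changes of −0.38 (SE 0.0417) and −0.46 (SE 0.0525). In chondroitin sulfate synthesis, 6 of 25 tested genes rose, 8 fell and 11 were not called (7 and 9 adjusted over the list alone, camera adjusted p = 0.741). CSGALNACT1 rose by a log2 fold change of 0.46 (SE 0.0776) and UST by 0.45 (SE 0.13), whereas CHSY1 fell by 0.29, a call lost with library size alone (adjusted p = 0.212).

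Integrin and protease genes moved in both directions. Of 30 tested integrin and focal adhesion genes, 6 rose, 12 fell and 12 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0645). ITGB3 fell from 699.4 ± 35.5 to 336.1 ± 17.6 CPM, although 51.6% of its exonic bases are also annotated to an overlapping gene. ITGA3 fell from 1199.8 ± 43.6 to 656.0 ± 20.8 CPM, and ITGA6, a laminin receptor subunit, rose from 126.2 ± 18.6 to 260.5 ± 17.5 CPM. Of 36 matrix proteases and inhibitors, 12 rose, 15 fell and 9 were not called, also with the list adjusted alone (camera adjusted p = 0.653). The collagenase MMP1 rose from 22.4 ± 1.2 to 43.4 ± 1.54 CPM, and the inhibitor TIMP3 fell from 94.8 ± 6.12 to 50.6 ± 4.69 CPM.

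More epithelial markers fell than rose, and mesenchymal transition genes moved in both directions. Of 26 tested epithelial markers, 16 fell, 1 rose and 9 were not called, the same when adjusted over the list alone, with a median log2 fold change of −0.46 (camera adjusted p = 6.53e-05, and adjusted p = 0.194 with an estimated correlation). E-cadherin (CDH1) fell from 16.5 ± 2.31 to 3.61 ± 0.814 CPM, keratin 7 (KRT7) from 308.2 ± 36.4 to 157.6 ± 14.1 CPM and claudin 4 (CLDN4) from 229.3 ± 9.84 to 137.4 ± 2.85 CPM. Of 29 mesenchymal transition genes, 6 rose, 9 fell and 14 were not called (7 and 10 adjusted over the list alone, camera adjusted p = 0.762). Their median and mean lay just above 0 (0.00094 and 0.0014) while the direction of the camera test was down. POSTN is in this list, and the transcription factor PRRX1 fell from 19.8 ± 1.45 to 5.72 ± 0.405 CPM and S100A4 from 309.2 ± 9 to 175.8 ± 7.03 CPM.

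Of 33 tested mitosis genes, 23 rose, none fell and 10 were not called (24 and 0 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 2.27e-06, and adjusted p = 0.203 with an estimated correlation). The mitotic kinase CDK1 rose from 109.0 ± 4.85 to 181.3 ± 13.7 CPM, survivin (BIRC5) from 163.1 ± 6.74 to 253.6 ± 5.88 CPM and UBE2C from 209.4 ± 8.81 to 299.4 ± 2.49 CPM. Of 40 DNA replication genes, 14 rose, 2 fell and 24 were not called, also adjusted over the list alone (camera adjusted p = 0.0279, and adjusted p = 0.203 with an estimated correlation). That call was lost without shGFP tumour 1 (adjusted p = 0.0646) and without shVCAN tumour 2 (adjusted p = 0.0645), over a range of 0.0069 to 0.0646 in all settings, and the median of 0.12 became 0.19 without shGFP tumour 2 and 0.28 with library size alone. Thymidylate synthase (TYMS) rose from 92.5 ± 5.99 to 137.9 ± 0.716 CPM and PCNA, the sliding clamp, from 119.5 ± 3.74 to 160.9 ± 7.27 CPM, while the helicase subunit MCM3 fell from 203.4 ± 5.91 to 145.3 ± 5.62 CPM. Of 73 ribosomal protein genes, 64 rose, none fell and 9 were not called (65 and 0 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 1.08e-15, and adjusted p = 0.194 with an estimated correlation). RPL9 rose from 381.6 ± 11.9 to 813.0 ± 29.6 CPM and RPSA from 987.2 ± 18.2 to 1704 ± 32.2 CPM. Ribosomal protein genes have many processed pseudogenes that can share their reads. Across genes the fold changes fell with exonic length (Spearman −0.271 over 12141 genes, which are not independent replicates).

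**Figure D1:**
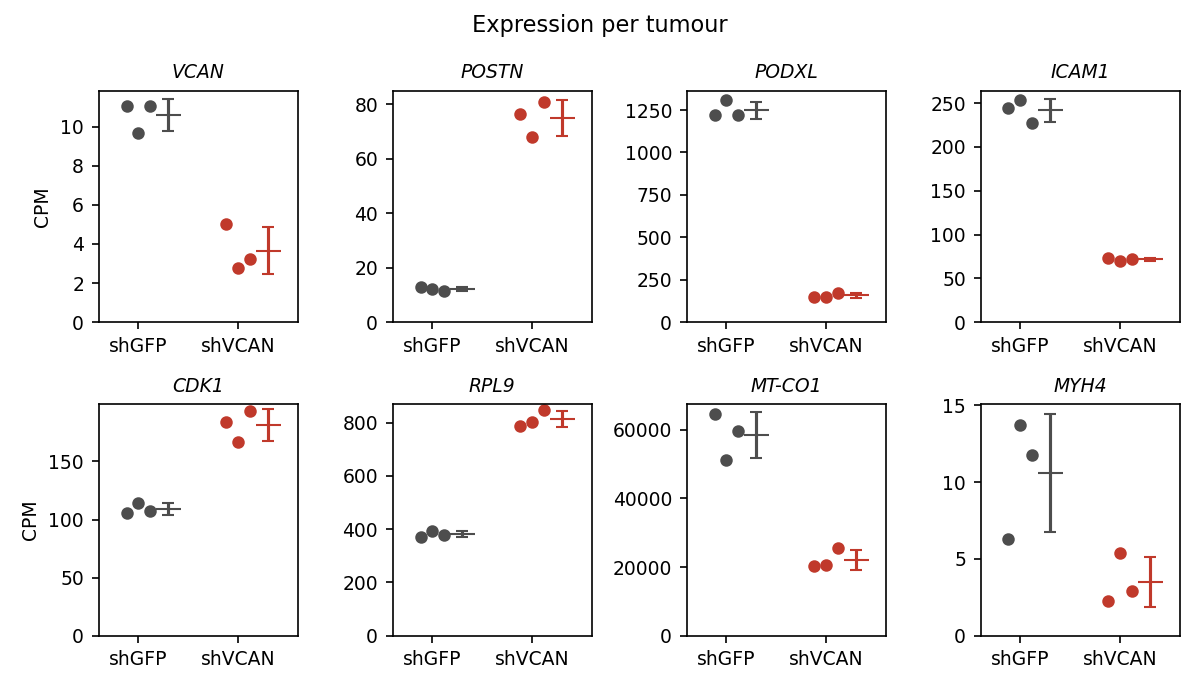
Expression of 8 genes in CPM (y axes, starting at 0) for each of the 3 shGFP and 3 shVCAN tumours (points), with the group mean and SD beside them (bars). Relative to its mean, MYH4, a muscle myosin, varies most within a group, 10.6 ± 3.84 CPM in shGFP and 3.51 ± 1.64 CPM in shVCAN. PODXL at 1249 ± 50.2 against 157.4 ± 13.2 CPM separates the groups widely.

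Of 27 EGFR and MAPK target genes, 16 fell, 2 rose and 9 were not called, the same when adjusted over the list alone (median −0.18, camera adjusted p = 0.000331, and adjusted p = 0.194 with an estimated correlation). With library size alone that median was −0.016. The early response and dissociation stress list, which shares 4 tested genes with it, had a median of −0.48 (camera adjusted p = 7.6e-05, and adjusted p = 0.194 with an estimated correlation). The pathway inhibitor SPRY4 fell from 195.7 ± 7.55 to 85.8 ± 6.91 CPM, cyclin D1 (CCND1) from 364.1 ± 7.72 to 214.7 ± 3.33 CPM and the EGFR ligand AREG from 40.05 ± 4.43 to 20.8 ± 2.80 CPM. Of 24 TGF-beta targets and pathway genes, 15 fell, 6 rose and 3 were not called, the same adjusted over the list alone (median −0.41, camera adjusted p = 0.00771, and adjusted p = 0.194 with an estimated correlation). The ligand TGFB1 fell from 154.0 ± 3.75 to 91.3 ± 2.72 CPM and CCN2 from 390.7 ± 15.1 to 269.2 ± 12 CPM. Among 19 WNT targets, 3 rose, 5 fell and 11 were not called, also adjusted over the list alone (camera adjusted p = 0.371). The WNT inhibitor DKK1 fell from 203.8 ± 22.1 to 134.4 ± 3.57 CPM, and the hyaluronan receptor CD44 rose from 157.1 ± 4.37 to 218.0 ± 10.3 CPM.

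More inflammatory and angiogenic genes fell than rose. Of 33 inflammatory and NF-kappaB genes, 16 fell, 5 rose and 12 were not called, the same adjusted over the list alone (median −0.43, camera adjusted p = 0.0204, and adjusted p = 0.216 with an estimated correlation). The adhesion molecule ICAM1 fell from 241.9 ± 13.3 to 71.6 ± 1.95 CPM and the inhibitor NFKBIA from 177.2 ± 8.70 to 75.0 ± 2.22 CPM. The neutrophil chemokines CXCL6 and CXCL8 rose, from 71.0 ± 4.27 to 155.1 ± 15.9 CPM and from 75.1 ± 5.89 to 142.5 ± 15.5 CPM. Of 28 angiogenic factors and receptors, 14 fell, 4 rose and 10 were not called, the same adjusted over the list alone (median −0.46, camera adjusted p = 0.012, and adjusted p = 0.203 with an estimated correlation). The endothelial list, which shares 4 tested genes with the angiogenic list, had a median of −0.43 (camera adjusted p = 0.0279, and adjusted p = 0.203 with an estimated correlation). PDGFB fell from 113.5 ± 8.20 to 41.5 ± 2.79 CPM and the vessel-destabilising ligand ANGPT2 from 34.2 ± 1.33 to 11.4 ± 2.26 CPM. Among 39 interferon response genes, 5 rose, 16 fell and 18 were not called (6 and 16 adjusted over the list alone, camera adjusted p = 0.196). OAS3 fell from 86.7 ± 5.95 to 50.3 ± 3.87 CPM and BST2 from 7.96 ± 1.18 to 3.15 ± 1.17 CPM. Of 31 hypoxia response genes, 6 rose, 12 fell and 13 were not called, also adjusted over the list alone (camera adjusted p = 0.198). DDIT4 fell from 109.9 ± 9.43 to 38.03 ± 0.722 CPM and VEGFA from 122.4 ± 7.55 to 79.6 ± 6.65 CPM.

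Unfolded protein response genes were mostly lower, and metabolic lists moved both ways. Of 27 unfolded protein response genes, 17 fell, 2 rose and 8 were not called (18 and 3 adjusted over the list alone), with a median of −0.27 (camera adjusted p = 0.0036, and adjusted p = 0.203 with an estimated correlation). TRIB3 fell from 179.5 ± 7.31 to 105.2 ± 7.89 CPM, and the chaperone HSP90B1 rose from 2111 ± 86.2 to 2855 ± 68.4 CPM. Of 18 glycolysis genes, 6 rose, 2 fell and 10 were not called, also adjusted over the list alone (camera adjusted p = 0.371). PGK1 rose from 367.5 ± 9.83 to 480.1 ± 6.15 CPM, and the lactate exporter SLC16A3 fell from 236.7 ± 6.75 to 173.3 ± 13 CPM. In the cholesterol synthesis list, 5 of 25 genes rose, 10 fell and 10 were not called (7 and 10 adjusted over the list alone, camera adjusted p = 0.634). The transcription factor SREBF2 fell from 169.7 ± 4.94 to 119.6 ± 7.99 CPM and the reductase DHCR7 from 132.4 ± 5.79 to 95.85 ± 1.11 CPM. Of 26 p53 targets and apoptosis genes, 7 rose, 6 fell and 13 were not called (7 and 7 adjusted over the list alone, camera adjusted p = 0.927), with a median of 0.025 and a mean of −0.033 and a camera direction of up. The stress cytokine GDF15 fell from 61.3 ± 3.76 to 14.5 ± 2.10 CPM, and the apoptosis gene BID rose from 31.8 ± 3.53 to 58.5 ± 2.55 CPM.

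Lineage and RNA modification lists were not called by camera, while fry, which does not compare them with other genes, called the androgen receptor list (lower, adjusted p = 0.0386), the neuroendocrine list (higher, adjusted p = 0.0155) and the methyladenosine list (lower, adjusted p = 0.0349). Of 13 androgen receptor axis genes, 1 rose, 4 fell and 8 were not called, also adjusted over the list alone (camera adjusted p = 0.371), with a median of 0.0059, a mean of −0.12 and a camera direction of down. FOXA1 fell from 51.3 ± 2.73 to 33.4 ± 2.04 CPM and the glucocorticoid receptor NR3C1 from 53.3 ± 1.12 to 34.5 ± 5.44 CPM. Among 10 neuroendocrine markers, 3 rose, 2 fell and 5 were not called (4 and 2 adjusted over the list alone, camera adjusted p = 0.385). SCG2 led them, and the synaptic protein SNAP25 rose from 2.52 ± 0.629 to 7.95 ± 0.489 CPM. Of 22 genes of the N6-methyladenosine machinery, 3 rose, 6 fell and 13 were not called, also adjusted over the list alone (camera adjusted p = 0.385). The demethylase ALKBH5 fell from 155.2 ± 4.05 to 118.1 ± 4.83 CPM, the reader IGF2BP1 from 3.64 ± 1.05 to 1.18 ± 0.124 CPM, and RBM15B rose from 53.04 ± 0.85 to 73.6 ± 5.62 CPM. With library size alone the medians of the integrin, protease, chondroitin sulfate, hypoxia, cholesterol and methyladenosine lists lay above 0 (0.084, 0.094, 0.063, 0.0018, 0.15 and 0.13), and with upper quartile factors those of the cholesterol and methyladenosine lists did (0.024 and 0.00094).

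**Figure D2:**
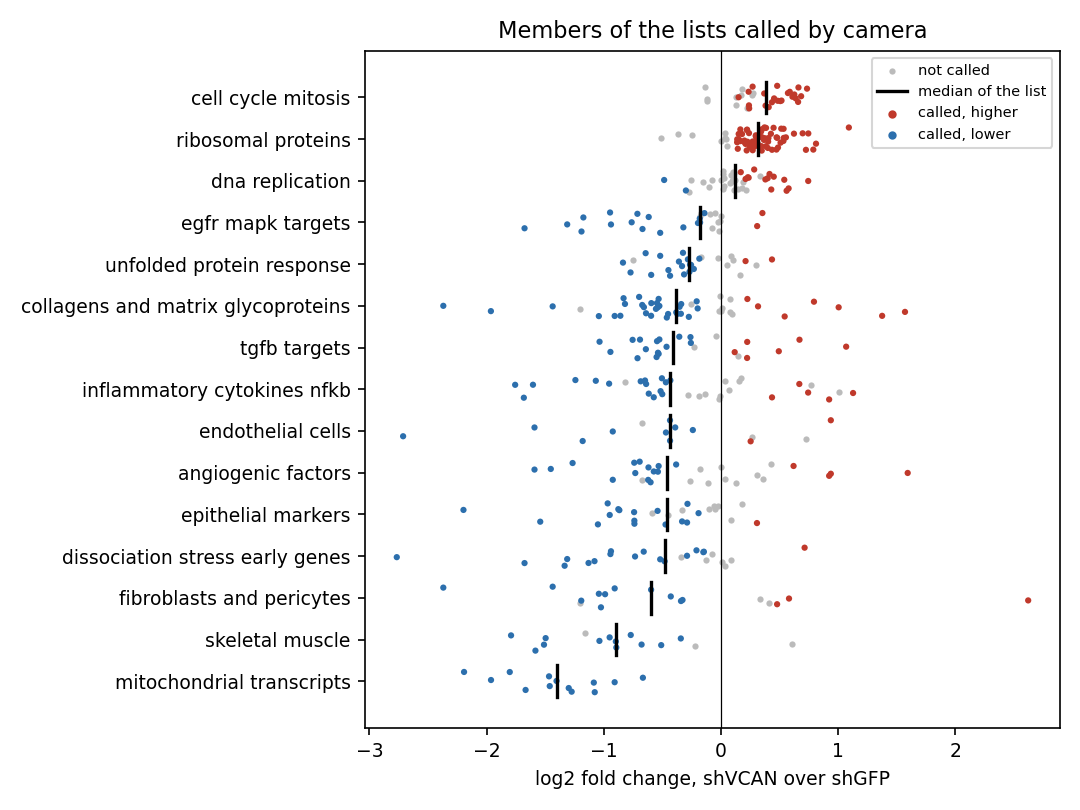
Log2 fold changes (shVCAN over shGFP, x axis) of the tested members of the 15 lists called by camera at the preset correlation (y axis), with grey points for members not called, red and blue points for members called higher or lower, and a black bar for the list's median. All 13 mitochondrial transcripts lie below 0, and 64 of 73 ribosomal protein genes are called higher.

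Lists of RNA quality and of other cell types also moved with the group. All 13 tested mitochondrial messenger RNAs fell, also adjusted over the list alone (median −1.40, camera adjusted p = 1.95e-09, and adjusted p = 0.237 with an estimated correlation). MT-ND1 had a log2 fold change of −1.46 (SE 0.0618) and MT-CO1 of −1.40 (SE 0.0616), while MT-ND4L and MT-ND4 overlap each other and have nuclear copies, as other mitochondrial genes do. An exact permutation test of the share of counts in the mitochondrial messenger RNAs gave p = 0.1, the smallest possible. Of 23 early response and dissociation stress genes, 16 fell, 1 rose and 6 were not called (17 and 1 adjusted over the list alone), with a median of −0.48 (camera adjusted p = 7.6e-05, and adjusted p = 0.194 with an estimated correlation). DUSP1 fell from 38.7 ± 1.19 to 18.3 ± 2.20 CPM and JUNB from 60.7 ± 4.13 to 31.6 ± 2.93 CPM, and the chaperone HSP90AA1 rose from 1356 ± 7.03 to 2223 ± 53.1 CPM. Of 5 tested members of the nuclear noncoding RNA list, 1 rose, 1 fell and 3 were not called, also adjusted over the list alone (camera adjusted p = 0.371). The 1 that rose was RN7SL1, like RN7SL3 an RNA of the signal recognition particle rather than a nuclear RNA. RN7SL1, whose exonic bases are all shared with another annotated gene, rose from 686.9 ± 79.5 to 3003 ± 124 CPM. Of 16 replication-dependent histone genes, 1 rose, 4 fell and 11 were not called, also adjusted over the list alone (camera adjusted p = 0.196), and H2BC12 fell from 71.1 ± 4.23 to 50.4 ± 2.53 CPM.

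Markers of stromal cells were mostly lower, and 10 of the 17 fibroblast and pericyte genes and 4 of the 14 endothelial genes are also in another list. Of 17 fibroblast and pericyte genes, 11 fell, 3 rose and 3 were not called (12 and 3 adjusted over the list alone), with a median of −0.60 (camera adjusted p = 0.00735, and adjusted p = 0.194 with an estimated correlation). COL1A1 fell from 618.8 ± 37.5 to 300.5 ± 48.9 CPM, beside the collagens named above and the rise of POSTN. Of 14 endothelial genes, 9 fell, 2 rose and 3 were not called, also adjusted over the list alone (median −0.43, camera adjusted p = 0.0279, and adjusted p = 0.203 with an estimated correlation). VE-cadherin (CDH5) fell from 5.87 ± 0.585 to 0.885 ± 0.277 CPM and the VEGF receptor KDR from 45.5 ± 2.63 to 24.0 ± 1.45 CPM. Of 15 skeletal muscle genes, 12 fell, none rose and 3 were not called (13 and 1 adjusted over the list alone), with a median of −0.90 (camera adjusted p = 0.0036, and adjusted p = 0.502 with an estimated correlation). Without shGFP tumour 3 that median was −0.54. Desmin (DES) fell from 25.7 ± 5.90 to 8.999 ± 2.32 CPM and NEB from 10.3 ± 3.84 to 2.96 ± 0.424 CPM.

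The remaining cell type lists were not called or too small for camera. Of 8 macrophage genes, 3 fell, none rose and 5 were not called, also adjusted over the list alone (camera adjusted p = 0.203). Camera called this list without shVCAN tumour 3 (adjusted p = 0.0231, over a range of 0.0231 to 0.279 in all settings). SPI1 fell from 32.9 ± 1.38 to 22.5 ± 3.88 CPM. Among 6 adipocyte genes, 1 rose, 2 fell and 3 were not called, also adjusted over the list alone (camera adjusted p = 0.878), and the fatty acid binding protein FABP4 rose from 4.45 ± 1.05 to 18.1 ± 0.861 CPM. Of 5 skin keratinocyte genes, 3 rose, 1 fell and 1 was not called, also adjusted over the list alone (camera adjusted p = 0.298), and KRT10 rose from 53.8 ± 1.91 to 72.9 ± 3.27 CPM. In the neutrophil list, S100A9 rose from 71.9 ± 9.11 to 96.5 ± 7.39 CPM, LCN2 fell from 2.43 ± 1.14 to 0.0714 ± 0.0706 CPM, and 1 of 3 genes was not called. In the lymphocyte list, IL7R fell from 63.8 ± 7.39 to 38.3 ± 3.99 CPM, CD8A rose from 1.41 ± 0.414 to 3.17 ± 0.23 CPM, and 1 of 3 genes was not called. The platelet integrin ITGA2B, the 1 erythroid and platelet gene tested, rose from 14.0 ± 0.657 to 18.3 ± 1.66 CPM, a call lost without shVCAN tumour 2 (log2 fold change 0.31, adjusted p = 0.0697). These 3 small lists had the same counts adjusted over the list alone.

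Camera with a preset correlation called 15 of 34 lists, 3 higher and 12 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.194, and 7 lists had an unadjusted p under 0.05. The self-contained test fry called 27. The estimated correlation was 0.806 for mitochondrial transcripts, 0.74 for skeletal muscle, 0.176 for ribosomal proteins and 0.124 for mitosis. These lie far above the preset 0.01, so the adjusted p of these lists at the preset may be much too small. Calls were lost also where the estimated correlation lay below the preset 0.01. For TGF-beta it was −0.0378 and for fibroblasts and pericytes −0.0258, yet the camera adjusted p went from 0.00771 and 0.00735 to 0.194. A lost call therefore does not by itself show that correlation between genes had made the call. With library size alone no called list changed direction, and the medians that moved by more than 1.5 times were, beside those of the EGFR and DNA replication lists, 0.48 for ribosomal proteins, −0.21 for the matrix list, −0.30 for epithelial markers, −0.32 for dissociation stress, −0.10 for the unfolded protein response, −0.24 for TGF-beta, −0.29 for angiogenic factors, −0.27 for inflammation and −0.27 for endothelial cells. The labels number the xenografts but do not say whether those of a group were separate tumours in separate mice. The p-values therefore measure the spread between these libraries, which may be less than that between tumours in separate mice. The group also cannot be separated from the pool of transduced cells that gave each set of libraries. Nor can versican loss be separated from any other effect of the hairpin, since the samples are labelled only shGFP or shVCAN.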

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

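The offset for length and GC content, with and without the block, and the scaling without mitochondrial genes were chosen after seeing the data. VCAN stayed lower and called in all 17 alternatives, with log2 fold changes from −1.36 to −1.83 and a largest adjusted p of 9.74e-06. With library size only, 5228 genes were higher and 1890 lower against 3120 and 3425 with TMM, because this scaling raises the median log2 fold change to 0.168. An absolute log2 fold change of at least 1 left 450 and 435 genes. The number of lists called went from 15 to 0 with an estimated correlation and to 27 with fry, which does not compare a list with other genes. Leaving out 1 tumour gave 2596 to 3086 higher genes, 2938 to 3438 lower genes and 14 to 16 lists. The replicate numbers did not pair the tumours, since the deviations of same-numbered tumours correlated at 0.052, 0.026 and −0.061 and not every tumour correlated best with its own number. With the replicate block 3083 genes were higher and 3428 lower, 15 lists were called and the log2 fold change of VCAN was −1.55. Of 146 named genes other than VCAN, 133 stayed on the same side of the threshold under each of the 17 refits in which they were tested. None changed direction, and the other 13 were lost in at least 1. The stricter bounds on fold change and on adjusted p were not applied to the named genes here. Library size only ended the calls of CHSY1, NDRG1, NEAT1, H2AC6, PPARG and DSC3, and leaving out 1 tumour ended, for at least 1 tumour, those of NEAT1, H2AC6, PPARG, KRT15, PMEPA1, H2BC9, LAPTM5, CD14, DSC3 and ITGA2B, where fewer tumours were compared. The length and GC offset ended the calls of NDRG1, NCAM1 and NEAT1 (log2 fold changes −0.040, −0.14 and −0.020). The glycolysis and histone lists were called only with that offset, with or without the block (adjusted p = 0.0227 for both, over ranges of 0.0227 to 0.576 and 0.0201 to 0.335), the integrin list with limma-voom or no filter (0.0123 and 0.0352, up to 0.94) and the hypoxia list with no filter (0.0392, up to 0.293), and the cause was not tested. Without shGFP tumour 1, SBSN had a log2 fold change of 4.81 in place of 3.07. Of simulated genes changed 1.5-fold, 65.3% were recovered, and how much of the loss was due to depth was not separated from the spread between tumours.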

Other observations

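The tests of scaling, of muscle reads and of fewer fibroblasts, and the genes and gene groups of the next paragraph, were chosen after the values were seen, as were the offset itself, the scaling without mitochondrial genes and the use of the fit without a filter for GABBR1. The bounds of the tests on length and GC content, on mitochondrial counts as a source of the scale and on PTBP1 targets were set before their results were computed, for patterns already seen.

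The splicing repressor PTBP1 fell from 322.9 ± 8.20 to 177.7 ± 5.63 CPM, and its paralog PTBP2, which prevails in neurons, rose from 22.2 ± 1.5 to 79.0 ± 4.23 CPM (edgeR adjusted p = 1.68e-14 and 4.07e-17). Of 76 nuclear genes for oxidative phosphorylation, 53 were higher and 1 lower, with a median log2 fold change of 0.39 that became 0.24 after the offset for length and GC content, when 45 were higher. COX7C rose from 327.2 ± 3.63 to 500.7 ± 12.8 CPM and NDUFA4 from 117.5 ± 1.32 to 192.1 ± 14.6 CPM. Of 72 genes for mitochondrial ribosomal proteins, 55 were higher and 1 lower, with a median of 0.37 that became 0.24 after the offset, when 43 were higher. No test against other genes was made for these 2 groups. Beside MUC5B, the secreted proteins SLPI and TFF3 fell from 19.0 ± 1.22 to 3.70 ± 0.536 CPM and from 22.4 ± 3.59 to 5.64 ± 0.364 CPM. Medians of the fold change over windows of 40 neighbouring genes varied with an SD of 0.0922 across 293 windows, against at most 0.0767 in 100 shuffles, and 0.072 against 0.0666 after the offset.

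PTBP1 is known to hold down productive transcripts of PTBP2, DLG4, GABBR1 and PTBP3, so the hypothesis was that lower PTBP1 may have released them. The bound set in advance asked for at least 2 of DLG4, GABBR1 and PTBP3 to rise, and 1 did. PTBP3 had a log2 fold change of 0.31 (adjusted p = 0.0012) and DLG4 of −0.12 (adjusted p = 0.25). GABBR1 had 2 to 10 counts per tumour and fell below the count filter, so it was taken from the fit without a filter (log2 fold change 0.27, adjusted p = 0.871). At such a depth a large rise could be called. MMP7 had one in the main fit, from 0.42 ± 0.29 to 1.73 ± 0.311 CPM (edgeR adjusted p = 0.0021). A smaller rise of GABBR1 could have been missed. Of the 2 targets above the count filter 1 rose, so the bound was not met but the release stays open. Splicing itself was not analysed here.

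Chance was tested by all 10 splits of the 6 tumours into 3 and 3, which are too few for a share under 0.05. Of these splits, 1 gave as many called genes as the groups, the real one with 6545, and the highest other gave 0. For lists, 1 split gave as many as the 15 called, again the real one, and the highest other gave 7. Every split but the real one mixes shGFP and shVCAN tumours on each side. The difference between the groups then counts as spread within a side, which hinders calls. The 0 genes and 7 lists are therefore not levels that chance alone would give, and the splits decide nothing about chance.

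Of 73 ribosomal protein genes 64 rose, and the median log2 fold change of the list was 0.32. After the offset for length and GC content the median was 0.25 (0.2476), and the bound set for that trend was not met. Camera still called the list at the preset correlation (without the offset, adjusted p = 0.194 with an estimated correlation). The offset used the length of all annotated exons (5022 bases for RPL9 and 5584 for RPS7), which can exceed that of the messenger RNA. It may therefore miss a trend with transcript length in these genes, and that trend stays open. Leaving out mitochondrial genes gave a median of 0.3177 but moved other genes as little, so that test decides nothing about the fall of mitochondrial counts. A shift of the scale would move all genes alike. The median of all tested genes was 0.00136 with TMM and 0.168 with library size alone, and the ribosomal median 0.3186 and 0.4842. These medians argue against a shift of the scale as the whole source. Reads shared with pseudogenes, a difference between the cell pools and another effect of the hairpin stay open, beside an effect of versican loss. The offset may also not remove the whole trend.

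All 13 mitochondrially encoded messenger RNAs fell, with a median of −1.40 (list adjusted p = 0.237 with an estimated correlation). The scaling nearest to no change gave −1.236, so the scalings tried did not produce the fall. The offset for length and GC content moved their median to −1.63, which argues against the trend as fitted. That trend was fitted on genes outside all lists and may not cover mitochondrial transcripts. For mouse muscle reads, the muscle median differed by 0.811 between the shGFP tumours with most and least of it, and the mitochondrial median by −0.111 between the same tumours, but from shGFP tumour 2 to 3 both were higher (muscle 0.50 and 0.75, mitochondrial 0.52 and 0.74, relative to the mean of each gene). Against them, shVCAN tumour 2 had a higher muscle median than shGFP tumour 1 (0.056 and −0.062) and a lower mitochondrial one (−0.78 and 0.85), and the median log2 fold change of the muscle list was −0.90. Muscle reads stay open because these are few tumours and how mouse reads of each kind align is unknown, as does RNA quality or handling that differed between the groups, since the labels give no batch.

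Of 15 skeletal muscle genes 12 fell, and of 17 fibroblast and pericyte genes 11 fell (adjusted p = 0.502 and 0.194 for the lists with an estimated correlation, and 0.066 for muscle with fry), and the muscle median of shVCAN tumour 2 (0.056) lay above that of shGFP tumour 1 (−0.062). Within groups the muscle markers varied together, with a mean correlation of 0.74 against at most 0.224 in 1000 random lists of like expression, which is consistent with muscle reads in amounts that vary per tumour and may come from host tissue. The length and GC offset left medians of −0.8144 for muscle and −0.5435 for fibroblasts and pericytes, which argues against that trend as fitted on exonic length. Fewer host fibroblasts alone would lower the members alike, but 3 rose (POSTN, RGS5 and NOTCH3) while 11 fell, so for the members that fell it stays open. Of the tested members, ACTA1 was the most abundant muscle gene at 202.3 ± 55.9 and 141.8 ± 32.8 CPM.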
